A study of Arabidopsis thaliana with 24 samples.

How the data were processed

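The deposited table holds, per the labels, 1 column of expected counts per library, made by the authors with RSEM 1.3.1 before deposit, with the aligner, genome build and annotation not given. The expected counts were rounded, and 98.3% of them were whole as deposited. The columns of FPKM, TPM, normalized values and averages in the same table were not used. The table held 24497 genes, of which 24424 were matched by gene ID to the reference table for symbols, and 73 organelle gene IDs were not. Of the genes tested, 8521 had a symbol, and the rest were counted but not named. The labels put each of the 24 libraries in 1 of 8 groups by genotype and medium, with 3 replicates each. They give the time on spectinomycin as 16 h in the treatment protocol and as 24 h in the series design, and the difference was not resolved. Their batch tag had 1 value per group, so that no batch correction could be fitted.

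All 24 libraries entered 1 edgeR 4.0.16 model in R 4.3.3, with 1 mean per group, TMM normalization and robust quasi-likelihood F tests. The filter filterByExpr, with a minimum count of 10 and a minimum total of 15, kept 19567 genes and left out 4930. The common biological coefficient of variation was 0.0466, with 16 residual degrees of freedom and a prior of 25.3. The 13 contrasts were the response of each genotype, the response of each altered genotype minus that of WT, and each altered genotype against WT on either medium, and p-values were adjusted by Benjamini-Hochberg within a contrast at 0.05. A gene is said to rise, fall, differ or change where it passed that threshold, and not to be called where it did not. Log2 fold changes are fitted values with their SE, and CPM use TMM library sizes. Correlations across genes, and the sets of genes that changed at least 2-fold in WT, were set against 20 simulations of unchanged groups that share the same WT libraries, the latter after seeing the data.

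The 30 gene lists were fixed before the data were examined: 28 lists of 401 genes, 400 of them in the table, and the plastid-encoded and mitochondrion-encoded genes. They cover nuclear photosynthesis, tetrapyrrole synthesis, plastid ribosomal proteins, plastid transcription, plastid chaperones and proteases, fatty acid synthesis, ER unfolded-protein genes, mitochondrial dysfunction, oxidative-stress transcription factors, indole defence, phenylpropanoids, iron deficiency, ferritin, ethylene, auxin, type-A response regulators, abscisic acid, jasmonate and salicylate, DNA damage, G2 and M phase, S phase, cyclin-dependent kinase inhibitors, and markers of the stem cell niche, root cap, endodermis, root hair, xylem and phloem. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, 2-sided, adjusted over the lists within a contrast, and again with an estimated correlation. Camera compares the members of a list with the other genes, and fry asks whether the members moved one way on balance.

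The rule for named genes was fixed before the data were examined. It always takes GUN1 and NAC103, and for each contrast the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 1 CPM in a group and no overlap between the groups' libraries, or 5 and 5 for NAC103-OX and for control medium. For the responses minus the WT response, the response had to differ in sign or by over 1 log2 unit. From each list it takes up to 3 called members with the smallest p. Of the genes the rule takes, the report names a part, chosen after the values were seen, mostly genes whose call and size held in every setting tried, and it says where they did not. RBCS1A, the leaf transcripts and the families in the closing section lie outside the rule. Genes with close copies, such as the RBCS genes, CYP71A12 and CYP71A13, may share reads.

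For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over that group, and for 1 to 3 counts the ratio carries a 95% interval by the exact (Clopper-Pearson) method. These intervals and floors cover counting error only. The test was run first on simulated changes in 19374 genes, with 50 genes changed at each fold. For the WT response it recovered 16 at 1.2-fold, 39 at 1.5-fold, 46 at 2-fold and 49 at 4-fold, with 7 false calls, and for the gun1-101 response minus the WT response 8 at 1.2-fold, 28 at 1.5-fold, 43 at 2-fold and 48 at 4-fold, with 5 false calls. In the gun1-101 response, where no change was simulated, it gave 0 false calls. Small changes, and differences of responses most of all, were therefore often missed.

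The alternatives tried were DESeq2 1.42.0 with its Wald test, edgeR RLE size factors, no filter beyond a count above 0, nuclear genes only, a fit with only the groups of the contrast, a replicate block, raw library sizes for the CPM of GUN1 and NAC103, and leaving out each replicate in turn, and for lists the estimated correlation (with statmod 1.5.0) and fry. A pseudocount on FPKM or TPM did not apply to counts. No gene or library was left out of the main fit beyond the filter. Alleles and reads were not examined.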

Results

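Poly(A) RNA was sequenced from root tips of about 0.5 cm of Arabidopsis seedlings, moved at about 5 days to medium with 10 mg/L spectinomycin, an antibiotic that blocks translation in plastids, or kept on control medium. Per the labels the incubation lasted 16 h in the treatment protocol and 24 h in the series design. The 4 genotypes were wild type (WT), gun1-101, a mutant of GUN1, whose product is a plastid pentatricopeptide-repeat protein of plastid-to-nucleus signalling, nac103-11, a mutant of NAC103, a NAC transcription factor tied to the unfolded protein response, and NAC103-OX, which carries a 35S promoter NAC103-GFP transgene. Each genotype and medium made 1 group of 3 libraries, so that 24 libraries fell into 8 groups. Library totals on control medium were 13837483 to 17059084 counts in WT, 13012580 to 15768845 in gun1-101, 14115909 to 16661719 in nac103-11 and 14419997 to 15286790 in NAC103-OX. On spectinomycin they were 14568694 to 17060225 in WT, 14303942 to 15777905 in gun1-101, 15118652 to 17411876 in nac103-11 and 15909168 to 15991059 in NAC103-OX. Levels are given in CPM (counts scaled to the normalized library size) as mean ± SD over 3 libraries, log2 fold changes as value ± SE, and p-values come from edgeR's quasi-likelihood test, adjusted by Benjamini-Hochberg over 19567 genes. For gene lists, the adjusted p is that of limma's camera test over 30 lists. Every list is given for the WT response, and for each other comparison the called lists with the 3 smallest p.

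GUN1 (AT2G31400) stood at 148 ± 3.55 CPM in WT and 85.8 ± 6.94 CPM in gun1-101 on control medium (log2 fold change -0.79 ± 0.048, adjusted p = 5.33e-18), and at 141 ± 3.54 and 78.6 ± 1.92 CPM on spectinomycin (log2 fold change -0.84 ± 0.048, adjusted p = 2.16e-19). GUN1 transcript was lower but still abundant in gun1-101, and its level in nac103-11 and NAC103-OX lay between 143 and 163 CPM. NAC103 (AT5G64060) was low in WT root tips, at 0.764 ± 0.141 CPM, and stood at 17.4 ± 0.707 CPM in NAC103-OX on control medium (log2 fold change 4.48 ± 0.16, adjusted p = 1.89e-26) and 20.06 ± 0.471 CPM on spectinomycin (log2 fold change 5.15 ± 0.16, adjusted p = 3.93e-27). In nac103-11 it was 0.617 ± 0.138 CPM on control medium, not called against WT (log2 fold change -0.31 ± 0.33, adjusted p = 0.515), and 0.0804 ± 0.0701 CPM on spectinomycin, against 0.558 ± 0.0391 in WT (log2 fold change -2.72 ± 0.53, adjusted p = 9.41e-05), where its libraries held 0 to 2 counts. The nac103-11 response of NAC103 was lower than that of WT (difference -2.41 ± 0.65, adjusted p = 0.0113), but not without nac103-11 spectinomycin replicate 2 (adjusted p = 0.0999). In WT, spectinomycin changed neither GUN1 (log2 fold change -0.071 ± 0.046, adjusted p = 0.225) nor NAC103 (log2 fold change -0.46 ± 0.32, adjusted p = 0.30). A count cannot show whether the remaining transcripts were intact, and the transgene and the endogenous NAC103 were counted together.

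**Figure D1:**
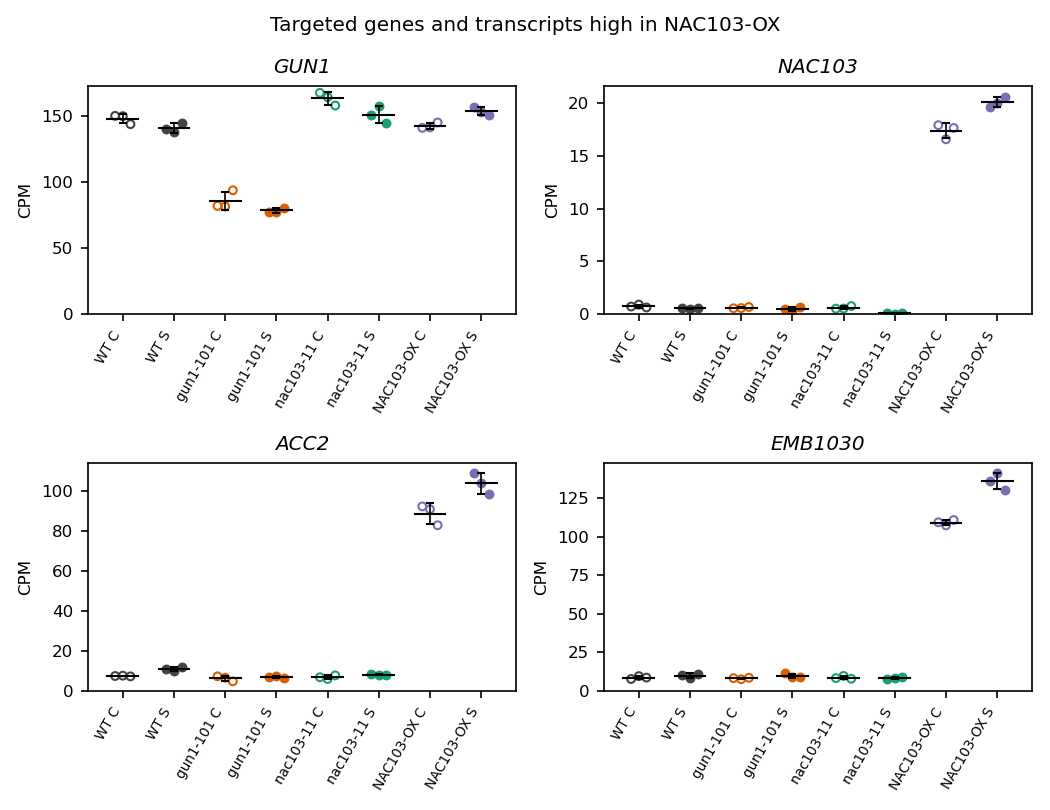
Levels of GUN1, NAC103, ACC2 and EMB1030 in CPM (vertical axis) in the 8 groups (horizontal axis), with 1 point per library and the mean ± SD. GUN1 lay at 85.8 and 78.6 CPM in gun1-101, and NAC103 at 17.4 and 20.06 CPM in NAC103-OX.

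The first principal component held 68.1% of the variance among the libraries and the second 7.95%. WT control replicate 2 stood apart from the other 2 WT control libraries: the chi-square per degree of freedom of its gene counts was 8.90 against replicate 1 and 9.02 against replicate 3, against 1.81 between those 2. Photosynthesis transcripts took part in this. RBCS1A, a small subunit of Rubisco chosen after its values were seen, had 123 CPM in replicate 2, 50.2 CPM in replicate 1 and 52.3 CPM in replicate 3. Values without this library are given beside the photosynthesis list. Without it the tetrapyrrole synthesis genes had an adjusted p of 0.00398 in the WT response and 0.0355, 6.88e-04 and 0.00294 in the responses of gun1-101, nac103-11 and NAC103-OX minus WT, against 0.0355, 0.242, 0.0270 and 0.0230 with all libraries, where no call was kept with an estimated correlation (0.387, 0.404 and 0.426 in WT and in the last 2). The phloem markers had 0.0180, 0.00451 and 0.0190 in the responses minus WT, against 0.162, 0.128 and 0.176. Root hair markers were called in the gun1-101 response minus WT without it (0.0235, against 0.393) and type-A response regulator genes in that of NAC103-OX were not (0.0644, against 0.0488). On control medium, 4 more lists were called without it in gun1-101, phloem markers (0.0116), fatty acid synthesis genes (0.0314), root cap markers (0.0431) and DNA damage genes (0.0461), and in nac103-11 phloem markers (0.0186) and tetrapyrrole synthesis genes (0.0316) were. The batch tag in the labels had a different value in each of the 8 groups, so that no batch held libraries of more than 1 group, and batch and group cannot be told apart.

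**Figure D2:**
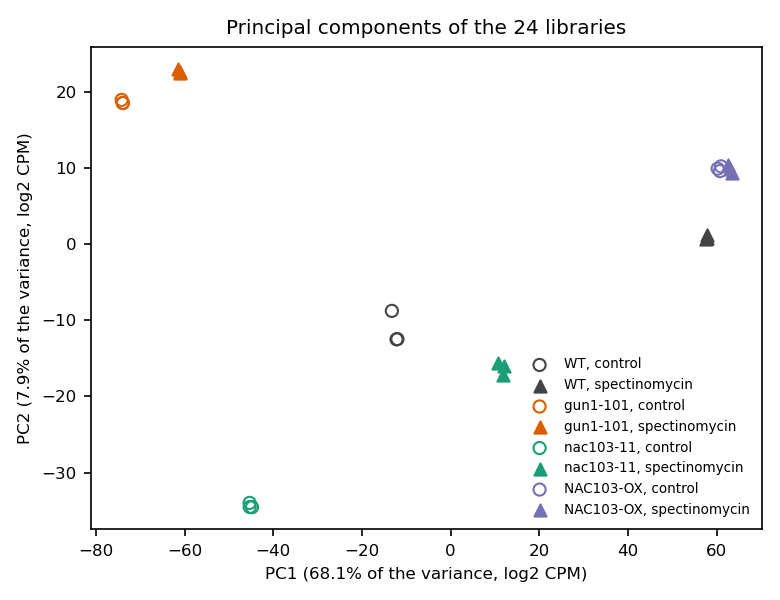
Principal components of log2 CPM, the first (68.1% of the variance) on the horizontal axis and the second (7.95%) on the vertical axis, with 1 point per library. Open circles are control medium and filled triangles spectinomycin, and colours are the 4 genotypes.

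In WT root tips on spectinomycin, PER4 (AT1G14540), a class III peroxidase, went from 285 ± 30.6 to 1.27 ± 0.406 CPM (log2 fold change -7.78 ± 0.10, adjusted p = 2.07e-36), and CYP71A12 (AT2G30750), a P450 of the camalexin route, went from 555 ± 43.4 to 4.95 ± 0.0751 CPM (log2 fold change -6.81 ± 0.074, adjusted p = 1.60e-45). CYP81F2 (AT5G57220), which hydroxylates indole glucosinolates, went from 404 ± 51.6 to 5.49 ± 0.233 CPM (log2 fold change -6.19 ± 0.086, adjusted p = 2.31e-34), and the nitrate reductase NIA1 (AT1G77760) went from 61.6 ± 11.1 to 0.884 ± 0.332 CPM (log2 fold change -6.13 ± 0.20, adjusted p = 6.22e-18). GSTU12 (AT1G69920) and ASPGB1 (AT3G16150), a glutathione transferase and an asparaginase, fell as well (log2 fold changes -5.95 ± 0.14 and -5.70 ± 0.091, highest adjusted p = 4.20e-28), and CYP71A18 (AT1G11610) was 238-fold (95% counting interval 81.1 to 1157) lower. The thalianol synthase THAS1 (AT5G48010) went from 30.9 ± 3.14 to 123 ± 4.08 CPM (log2 fold change 1.99 ± 0.058, adjusted p = 1.33e-29), and the sterol desaturase CYP710A2 (AT2G34490), the nitrate transporter gene NRT2.6 (AT3G45060) and CSLB04 (AT2G32540) rose from lower levels (log2 fold changes 2.57 ± 0.18, 2.71 ± 0.24 and 2.28 ± 0.32, highest adjusted p = 9.73e-08). In all, 7940 genes changed, 3939 up and 4001 down (2559 and 3596 with only the groups of the contrast), and 208 rose and 892 fell at least 2-fold.

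**Figure D3:**
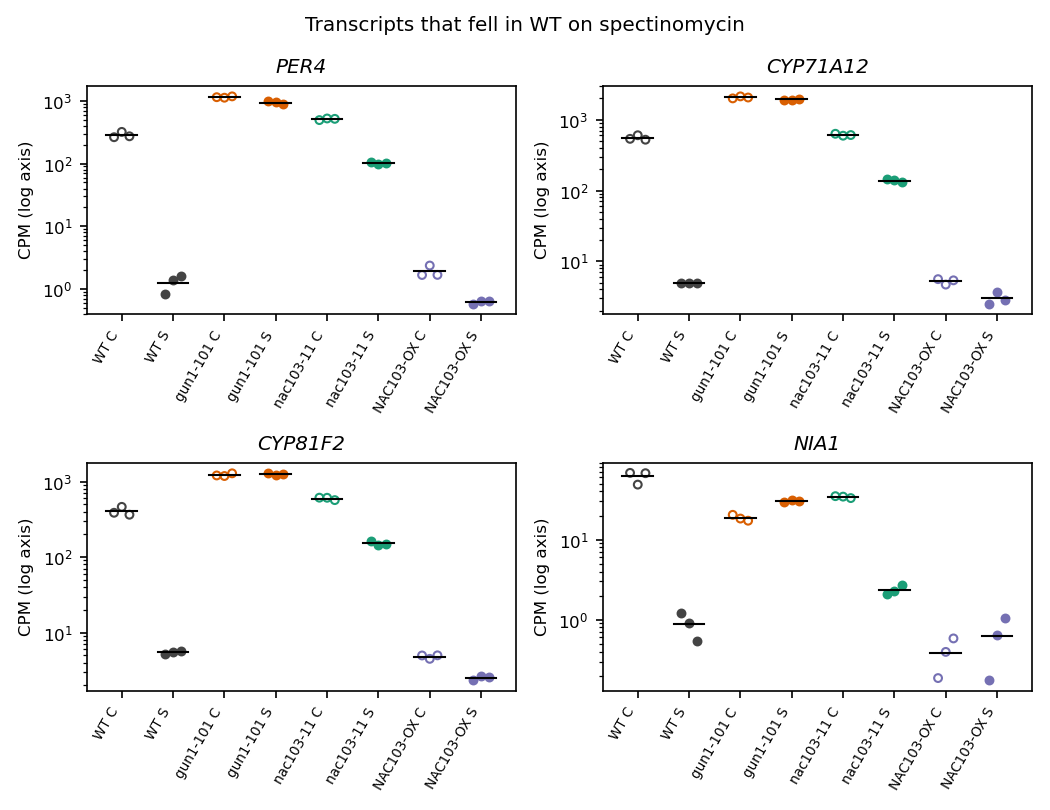
Levels of named genes in CPM (vertical axis, log scale) in the 8 groups (horizontal axis), with 1 point per library and a line at each mean. PER4 lay at 285 CPM in WT on control medium and 1.27 CPM on spectinomycin, and at 939.6 CPM in gun1-101 on spectinomycin.

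Among photosynthesis genes in WT, PSBO2 (AT3G50820), PSBO1 (AT5G66570) and LHCB4.2 (AT3G08940), of the oxygen-evolving complex and a light-harvesting antenna, rose (log2 fold changes 1.80 ± 0.091, 1.01 ± 0.074 and 0.91 ± 0.084, highest adjusted p = 5.06e-12), and RBCS1B (AT5G38430), of the Rubisco small subunit with near-identical tandem copies, went from 0.122 ± 0.0504 to 1.92 ± 0.539 CPM (log2 fold change 3.83 ± 0.44, adjusted p = 8.14e-10). Among the 50 nuclear photosynthesis genes measured, 43 rose, 2 fell and 5 were not called (46 and 2 adjusted over the list alone). Their median was 0.67 (adjusted p = 8.28e-13, and adjusted p = 0.219 with an estimated correlation). WT control replicate 2 was the WT control library with the highest RBCS1A, and without it the list's median was 1.00 (adjusted p = 6.01e-24). Within tetrapyrrole synthesis, the ferrochelatase FC1 (AT5G26030) and the glutamyl-tRNA reductase HEMA2 (AT1G09940) fell while GUN5 (AT5G13630), of the Mg-chelatase, rose (log2 fold changes -0.82 ± 0.051, -1.04 ± 0.074 and 0.66 ± 0.056, highest adjusted p = 1.57e-13). Of the 22 tetrapyrrole synthesis genes measured, 10 rose, 4 fell and 8 were not called (12 and 4 adjusted over the list alone). Their median was 0.30 (adjusted p = 0.0355, and adjusted p = 0.387 with an estimated correlation). Their adjusted p was 0.0724 without WT control replicate 1 and 0.0936 without WT control replicate 3. Among the 32 nuclear genes of plastid ribosomal proteins measured, 17 rose, 0 fell and 15 were not called (19 and 0 adjusted over the list alone). Their median was 0.22 (adjusted p = 5.97e-05, and adjusted p = 0.0637 with an estimated correlation). Of the 8 nuclear genes of plastid transcription measured, 6 rose, 0 fell and 2 were not called (6 and 0 adjusted over the list alone). Their median was 0.23 (adjusted p = 0.104). Their adjusted p was 0.0406 without WT control replicate 2. Among the 13 plastid chaperone and protease genes measured, 3 rose, 3 fell and 7 were not called (4 and 3 adjusted over the list alone). Their median was 0.066 (adjusted p = 0.497). The plastid chaperonin gene CPN60A (AT2G28000) was among those that rose (log2 fold change 0.50 ± 0.047, adjusted p = 4.20e-12). Of the 10 fatty acid synthesis genes measured, 1 rose, 1 fell and 8 were not called (1 and 1 adjusted over the list alone). Their median was 0.079 (adjusted p = 0.541).

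Plastid-encoded genes took 0.000630 to 0.00138% of the counts of a library. Among the 4 plastid-encoded genes measured, 0 rose, 0 fell and 4 were not called (0 and 0 adjusted over the list alone). Their median was 0.47 (adjusted p = 0.535). Of the 5 mitochondrion-encoded genes measured, 1 rose, 0 fell and 4 were not called (1 and 0 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.541).

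Among stress genes, BZIP60 (AT1G42990), CNX1 (AT5G61790) and BIP2 (AT5G42020), a transcription factor and chaperones of the endoplasmic reticulum (ER), dropped (log2 fold changes -1.10 ± 0.057, -0.77 ± 0.044 and -0.73 ± 0.047, highest adjusted p = 2.03e-17), and so did the transcription factor genes ERF6 (AT4G17490), STZ (AT1G27730) and WRKY33 (AT2G38470) (log2 fold changes -2.95 ± 0.068, -3.20 ± 0.080 and -2.43 ± 0.071, highest adjusted p = 1.22e-22). CYP81D8 (AT4G37370), NDB2 (AT4G05020) and BCS1 (AT3G50930), used as markers of mitochondrial dysfunction, fell (log2 fold changes -4.05 ± 0.10, -1.28 ± 0.070 and -2.25 ± 0.12, highest adjusted p = 4.34e-19), and MYB51 (AT1G18570) and CYP83B1 (AT4G31500) of indole glucosinolate synthesis fell too (log2 fold changes -2.17 ± 0.049 and -1.21 ± 0.043, highest adjusted p = 3.11e-26). Among the 32 ER unfolded-protein genes measured, 1 rose, 23 fell and 8 were not called (1 and 23 adjusted over the list alone). Their median was -0.46 (adjusted p = 1.17e-09). Of the 17 mitochondrial dysfunction genes measured, 1 rose, 15 fell and 1 was not called (1 and 15 adjusted over the list alone). Their median was -1.08 (adjusted p = 9.13e-10). Among the 7 oxidative-stress transcription factor genes measured, 0 rose, 7 fell and 0 were not called (0 and 7 adjusted over the list alone). Their median was -1.35 (adjusted p = 1.19e-09). Of the 8 indole defence genes measured, 1 rose, 6 fell and 1 was not called (1 and 6 adjusted over the list alone). Their median was -1.10 (adjusted p = 1.57e-04). Among the 12 phenylpropanoid genes measured, 2 rose, 7 fell and 3 were not called (2 and 9 adjusted over the list alone). Their median was -0.39 (adjusted p = 7.02e-04). PAL1 (AT2G37040) and PAL2 (AT3G53260), at the entry of that route, fell (log2 fold changes -1.56 ± 0.046 and -1.44 ± 0.048, highest adjusted p = 1.73e-27), as did F6'H1 (AT3G13610), of coumarin synthesis (log2 fold change -4.98 ± 0.057, adjusted p = 1.25e-44). Of the 15 iron deficiency genes measured, 1 rose, 3 fell and 11 were not called (1 and 3 adjusted over the list alone). Their median was -0.19 (adjusted p = 0.222). Among the 3 ferritin genes measured, 2 rose, 0 fell and 1 was not called (2 and 0 adjusted over the list alone). Their median was 0.19 (adjusted p = 0.356).

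Among hormone genes, the ethylene synthesis gene ACS6 (AT4G11280), the auxin conjugation gene GH3.3 (AT2G23170) and the jasmonate repressor gene JAZ1 (AT1G19180) fell (log2 fold changes -2.18 ± 0.075, -2.19 ± 0.11 and -1.65 ± 0.055, highest adjusted p = 7.37e-21), while the cytokinin response regulator genes ARR9 (AT3G57040) and ARR6 (AT5G62920) and the dehydration gene LTI78 (AT5G52310) rose (log2 fold changes 0.71 ± 0.060, 0.78 ± 0.074 and 1.18 ± 0.069, highest adjusted p = 6.11e-12). Of the 5 ethylene genes measured, 0 rose, 3 fell and 2 were not called (0 and 4 adjusted over the list alone). Their median was -0.63 (adjusted p = 0.00299). Among the 10 auxin genes measured, 2 rose, 6 fell and 2 were not called (2 and 6 adjusted over the list alone). Their median was -0.58 (adjusted p = 0.107). Of the 8 type-A response regulator genes measured, 6 rose, 1 fell and 1 was not called (6 and 1 adjusted over the list alone). Their median was 0.38 (adjusted p = 0.00424). Among the 7 abscisic acid genes measured, 4 rose, 0 fell and 3 were not called (4 and 0 adjusted over the list alone). Their median was 0.52 (adjusted p = 0.0156). Of the 6 jasmonate and salicylate genes measured, 1 rose, 3 fell and 2 were not called (1 and 3 adjusted over the list alone). Their median was -0.39 (adjusted p = 0.242).

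Among cell cycle genes in WT, E2F1 (AT5G22220) and SMR6 (AT5G40460) fell, and CYCD3;1 (AT4G34160) and KRP2 (AT3G50630) rose (log2 fold changes -0.58 ± 0.11, -1.14 ± 0.20, 0.46 ± 0.095 and 0.72 ± 0.16, highest adjusted p = 2.41e-04, in that order). Among the 17 DNA damage genes measured, 2 rose, 0 fell and 15 were not called (0 and 0 adjusted over the list alone). Their median was 0.090 (adjusted p = 0.516). Of the 26 G2 and M phase genes measured, 2 rose, 0 fell and 24 were not called (2 and 0 adjusted over the list alone). Their median was 0.11 (adjusted p = 0.295). Among the 23 S phase genes measured, 4 rose, 2 fell and 17 were not called (3 and 2 adjusted over the list alone). Their median was 0.14 (adjusted p = 0.417). Of the 16 cyclin-dependent kinase inhibitor genes measured, 5 rose, 1 fell and 10 were not called (5 and 1 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.516).

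No list of cell type markers was called in WT, with SUC2 (AT1G22710) of the phloem up and CASP2 (AT3G11550) of the endodermis down (log2 fold changes 0.29 ± 0.046 and -0.42 ± 0.090, highest adjusted p = 1.85e-04). Among the 7 stem cell niche markers measured, 2 rose, 1 fell and 4 were not called (2 and 1 adjusted over the list alone). Their median was 0.23 (adjusted p = 0.596). Of the 4 root cap markers measured, 0 rose, 1 fell and 3 were not called (0 and 0 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.541). Among the 9 endodermis markers measured, 1 rose, 2 fell and 6 were not called (1 and 2 adjusted over the list alone). Their median was 0.074 (adjusted p = 0.976). Their median, mean (-0.0012) and test (up) differed in sign. Of the 7 root hair markers measured, 0 rose, 1 fell and 6 were not called (0 and 1 adjusted over the list alone). Their median was -0.14 (adjusted p = 0.751). Among the 6 xylem markers measured, 2 rose, 0 fell and 4 were not called (2 and 0 adjusted over the list alone). Their median was 0.22 (adjusted p = 0.153). Of the 4 phloem markers measured, 2 rose, 0 fell and 2 were not called (2 and 0 adjusted over the list alone). Their median was 0.20 (adjusted p = 0.174). Their adjusted p was 0.0201 without WT control replicate 2. In the other comparisons, 6 marker lists were called with all libraries. They were endodermis markers (median -0.21, adjusted p = 0.00563, and 0.256 with an estimated correlation) in the gun1-101 response, xylem markers (median 0.36, adjusted p = 0.0347, and 0.0941 with an estimated correlation) in the nac103-11 response and root hair markers (median -0.38, adjusted p = 0.0120, and 0.336 with an estimated correlation) in gun1-101 on control medium. In NAC103-OX they were phloem markers (median 0.40, adjusted p = 0.0186, and 0.184 with an estimated correlation) on control medium, and endodermis markers (median 0.23, adjusted p = 0.00915, and 0.217 with an estimated correlation) and xylem markers (median -0.29, adjusted p = 6.27e-04, and 0.0115 with an estimated correlation) on spectinomycin.

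In gun1-101 the nitrate transporter gene NRT2.6 went from 18.2 ± 1.82 to 1.31 ± 0.405 CPM (log2 fold change -3.79 ± 0.17, adjusted p = 7.60e-21), where it rose in WT, and BAP2 (AT2G45760) and LCR67 (AT1G75830) fell as well (log2 fold changes -3.47 ± 0.41 and -3.29 ± 0.39, highest adjusted p = 4.04e-08). CYP71A13 (AT2G30770), a camalexin route gene with a near-identical copy, and GER2 (AT5G39190) rose (log2 fold changes 0.98 ± 0.10 and 0.97 ± 0.17, highest adjusted p = 4.42e-05), as did the plastid chaperone genes CR88 (AT2G04030) and CPN60A (log2 fold changes 0.47 ± 0.050 and 0.33 ± 0.049, highest adjusted p = 3.33e-06). The ethylene synthesis gene ACS2 (AT1G01480) and the response regulator genes ARR3 (AT1G59940) and ARR4 (AT1G10470) fell (log2 fold changes -1.20 ± 0.14, -0.67 ± 0.12 and -0.25 ± 0.050, highest adjusted p = 3.01e-04). In total 2189 genes changed in gun1-101, 631 up and 1558 down (1133 and 1811 with only the groups of the contrast, 407 and 1182 without gun1-101 control replicate 1), and 17 rose and 76 fell at least 2-fold. Of 30 lists 8 were called, 4 up and 4 down, and 3 kept the call with an estimated correlation. Among the 50 nuclear photosynthesis genes measured, 6 rose, 2 fell and 42 were not called (8 and 2 adjusted over the list alone). Their median was 0.22 (adjusted p = 2.24e-05, and adjusted p = 0.430 with an estimated correlation). Their directional adjusted p was 0.131 with fry. Of the 5 ethylene genes measured, 0 rose, 4 fell and 1 was not called (0 and 5 adjusted over the list alone). Their median was -0.29 (adjusted p = 3.41e-04). Among the 13 plastid chaperone and protease genes measured, 4 rose, 0 fell and 9 were not called (5 and 0 adjusted over the list alone). Their median was 0.10 (adjusted p = 3.41e-04, and adjusted p = 0.200 with an estimated correlation).

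Genes that fell far in WT moved little in gun1-101: PER4 went from 1148 ± 28.4 to 939.6 ± 51.1 CPM (difference from the WT response 7.49 ± 0.13, adjusted p = 5.22e-33), CYP71A12 from 2070.3 ± 68.1 to 1935 ± 27.7 CPM (difference 6.71 ± 0.089, adjusted p = 1.31e-41) and CYP81F2 from 1223 ± 53.6 to 1271 ± 32.4 CPM (difference 6.25 ± 0.10, adjusted p = 1.72e-31). NRT2.6 responded lower (difference -6.50 ± 0.30, adjusted p = 4.19e-22), and NIA1 and GSTU12 higher (differences 6.82 ± 0.25 and 5.63 ± 0.16, highest adjusted p = 2.29e-16). So did the transcription factor genes ERF6, STZ, WRKY33 and MYB51 (differences 2.78 ± 0.084, 2.84 ± 0.10, 2.24 ± 0.093 and 1.98 ± 0.064, highest adjusted p = 2.60e-18) and the ER genes BZIP60 and CNX1 (differences 0.99 ± 0.076 and 0.70 ± 0.062, highest adjusted p = 1.57e-12). The response differed from that of WT in 4801 genes, higher in 2681 and lower in 2120. Of the 892 genes that fell at least 2-fold in WT, 813 responded higher in gun1-101, where their median log2 fold change was -0.24 and 402 fell. Of the 208 that rose at least 2-fold, 128 responded lower, and 32 rose in gun1-101.

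Among photosynthesis genes, PSBO2 and RBCS1B responded lower in gun1-101 than in WT (differences -1.09 ± 0.14 and -4.33 ± 0.46, highest adjusted p = 6.92e-08). Of the 50 nuclear photosynthesis genes measured, 1 responded higher, 22 lower and 27 were not called (1 and 26 adjusted over the list alone). Their median was -0.48 (adjusted p = 2.28e-08, and adjusted p = 0.353 with an estimated correlation). Without WT control replicate 2, in which photosynthesis transcripts stood higher, the median was -0.76 (adjusted p = 2.61e-20). Of 30 lists 9 were called, 6 up and 3 down, and 6 kept the call with an estimated correlation. Among the 7 oxidative-stress transcription factor genes measured, 7 responded higher, 0 lower and 0 were not called (7 and 0 adjusted over the list alone). Their median was 1.25 (adjusted p = 1.49e-11). Of the 17 mitochondrial dysfunction genes measured, 14 responded higher, 0 lower and 3 were not called (14 and 0 adjusted over the list alone). Their median was 1.203 (adjusted p = 1.49e-11). Among the 32 ER unfolded-protein genes measured, 18 responded higher, 0 lower and 14 were not called (21 and 0 adjusted over the list alone). Their median was 0.37 (adjusted p = 2.59e-09).

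In nac103-11 on spectinomycin the nitrate transporter gene NRT1.8 (AT4G21680) went from 230.4 ± 0.958 to 19.4 ± 1.53 CPM (log2 fold change -3.56 ± 0.067, adjusted p = 8.74e-36), and NRT2.6 and NIA1 went down as well (log2 fold changes -3.32 ± 0.13 and -3.84 ± 0.18, highest adjusted p = 8.35e-15). BZIP60, CNX1, ERF6, WRKY33 and MYB51 fell too (log2 fold changes -0.85 ± 0.055, -0.64 ± 0.044, -2.07 ± 0.055, -1.70 ± 0.065 and -1.65 ± 0.045, highest adjusted p = 2.76e-16). CYP710A2 and the expansin gene EXPA17 (AT4G01630) rose (log2 fold changes 3.35 ± 0.22 and 3.09 ± 0.18, highest adjusted p = 2.56e-15), PSBO2 and LTI78 rose (log2 fold changes 1.48 ± 0.10 and 1.23 ± 0.076, highest adjusted p = 1.31e-15), and RBCS3B (AT5G38410), which has near-identical copies, went from 0.339 ± 0.156 to 10.7 ± 0.684 CPM (log2 fold change 4.92 ± 0.25, adjusted p = 8.59e-21). In total 8768 genes changed in nac103-11, 4194 up and 4574 down (4438 and 4357 with nuclear genes only), and 450 rose and 819 fell at least 2-fold. Of 30 lists 11 were called, 5 up and 6 down, and 3 kept the call with an estimated correlation. Of the 32 ER unfolded-protein genes measured, 0 rose, 23 fell and 9 were not called (1 and 24 adjusted over the list alone). Their median was -0.45 (adjusted p = 2.39e-08). Among the 50 nuclear photosynthesis genes measured, 34 rose, 3 fell and 13 were not called (35 and 3 adjusted over the list alone). Their median was 0.51 (adjusted p = 4.90e-08, and adjusted p = 0.311 with an estimated correlation). Of the 7 oxidative-stress transcription factor genes measured, 0 rose, 6 fell and 1 was not called (0 and 6 adjusted over the list alone). Their median was -1.26 (adjusted p = 2.15e-06).

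Against the WT response, PER4 and CYP71A12 fell less in nac103-11. PER4 went from 511 ± 15.7 to 103 ± 3.54 CPM (difference 5.47 ± 0.14, adjusted p = 4.57e-27) and CYP71A12 from 613 ± 19.6 to 138 ± 5.50 CPM (difference 4.66 ± 0.092, adjusted p = 1.33e-34). NAC042 (AT2G43000) and PXMT1 (AT1G66700), F6'H1 (AT3G13610), STZ and ERF6 also responded higher (differences 3.41 ± 0.14, 3.39 ± 0.15, 2.99 ± 0.072, 1.78 ± 0.10 and 0.88 ± 0.090, highest adjusted p = 4.89e-10). NRT2.6, NRT1.8 and UMAMIT14 (AT2G39510) and HA4 (AT3G47950) responded lower (differences -6.03 ± 0.27, -3.97 ± 0.12, -3.30 ± 0.34 and -1.70 ± 0.13, highest adjusted p = 6.37e-10). The response differed from WT in 2300 genes, higher in 1213 and lower in 1087. They were 1489 and 889 with nuclear genes only and 1319 and 772 without nac103-11 spectinomycin replicate 1. Of the 892 genes that fell at least 2-fold in WT, 818 fell in nac103-11 (median -1.25), and 434 responded higher than in WT. Of the 208 that rose at least 2-fold, 160 rose in nac103-11, with a median of 1.28, or 1.26 with genes at 0 counts in 1 group set to their bound. Of 30 lists 9 were called, 6 up and 3 down, and 3 kept the call with an estimated correlation. Among the 8 indole defence genes measured, 5 responded higher, 0 lower and 3 were not called (8 and 0 adjusted over the list alone). Their median was 0.43 (adjusted p = 8.62e-07). Of the 17 mitochondrial dysfunction genes measured, 10 responded higher, 1 lower and 6 were not called (12 and 1 adjusted over the list alone). Their median was 0.72 (adjusted p = 8.62e-07, and adjusted p = 0.0546 with an estimated correlation). Among the 7 oxidative-stress transcription factor genes measured, 4 responded higher, 0 lower and 3 were not called (6 and 0 adjusted over the list alone). Their median was 0.55 (adjusted p = 1.09e-06). The photosynthesis list was not called (median -0.10, adjusted p = 0.0627). Without WT control replicate 2, in which these genes stood higher, its median was -0.37 (adjusted p = 2.61e-10). Leaving out that library moves the list this way by design, so this is not taken as a call.

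In NAC103-OX few genes moved far on spectinomycin: PER4 went from 1.91 ± 0.400 to 0.622 ± 0.0357 CPM (log2 fold change -1.60 ± 0.28, adjusted p = 4.88e-04) and NRT2.6 went from 6.32 ± 0.871 to 2.55 ± 0.651 CPM (log2 fold change -1.31 ± 0.17, adjusted p = 2.81e-06). RBCS3B rose (log2 fold change 1.25 ± 0.27, adjusted p = 0.00404), and so did the ER chaperone genes BIP2 and CRT1a (AT1G56340) and the auxin transport gene EIR1 (AT5G57090) (log2 fold changes 0.29 ± 0.049, 0.22 ± 0.044 and 0.50 ± 0.055, highest adjusted p = 0.00161). In total 990 genes changed in NAC103-OX, 438 up and 552 down, and 15 rose and 14 fell at least 2-fold, 29 in all, against 8 with DESeq2 and 16 without NAC103-OX spectinomycin replicate 3. The number of changed genes was 646 and 524 without NAC103-OX control replicates 1 and 2, and 620, 540 and 483 without NAC103-OX spectinomycin replicates 1, 2 and 3. Of 30 lists 3 were called, 3 up and 0 down, and 2 kept the call with an estimated correlation. Of the 23 S phase genes measured, 5 rose, 0 fell and 18 were not called (9 and 0 adjusted over the list alone). Their median was 0.27 (adjusted p = 6.75e-05). Among the 10 auxin genes measured, 2 rose, 0 fell and 8 were not called (3 and 0 adjusted over the list alone). Their median was 0.23 (adjusted p = 0.00402). Of the 32 ER unfolded-protein genes measured, 7 rose, 0 fell and 25 were not called (10 and 1 adjusted over the list alone). Their median was 0.040 (adjusted p = 0.0164, and adjusted p = 0.216 with an estimated correlation). Their adjusted p was 0.0635 without NAC103-OX control replicate 2.

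Genes that fell in WT were already low in NAC103-OX on control medium and stayed low: NIA1 went from 0.388 ± 0.198 to 0.623 ± 0.440 CPM and PER4 from 1.91 ± 0.400 to 0.622 ± 0.0357 CPM (differences from the WT response 6.81 ± 0.75 and 6.18 ± 0.45, highest adjusted p = 1.46e-07). Without NAC103-OX spectinomycin replicate 3 the difference of NIA1 was 6.21. CNX1, BIP2, ERF6, MYB51 and ACS6 responded higher than in WT, where they fell (differences 0.99 ± 0.063, 1.03 ± 0.068, 3.04 ± 0.12, 2.31 ± 0.075 and 2.36 ± 0.12, highest adjusted p = 1.61e-16), and NRT2.6, BGLU7 (AT3G62740), PSBO2, LTI78 and emb1473 (AT1G78630), of the plastid ribosome, responded lower (differences -4.02 ± 0.30, -2.36 ± 0.30, -2.07 ± 0.12, -1.29 ± 0.090 and -0.77 ± 0.085, highest adjusted p = 1.90e-08). The response differed from WT in 6176 genes, higher in 3214 and lower in 2962. Of the 892 genes that fell at least 2-fold in WT, 44 fell and 28 rose in NAC103-OX (median -0.039), and of the 208 that rose, 11 rose. Of 30 lists 12 were called, 7 up and 5 down, and 9 kept the call with an estimated correlation. Among the 50 nuclear photosynthesis genes measured, 1 responded higher, 36 lower and 13 were not called (1 and 43 adjusted over the list alone). Their median was -0.81 (adjusted p = 7.08e-12, and adjusted p = 0.248 with an estimated correlation). Of the 7 oxidative-stress transcription factor genes measured, 6 responded higher, 0 lower and 1 was not called (7 and 0 adjusted over the list alone). Their median was 1.41 (adjusted p = 5.94e-10). Among the 32 ER unfolded-protein genes measured, 20 responded higher, 2 lower and 10 were not called (22 and 2 adjusted over the list alone). Their median was 0.49 (adjusted p = 8.67e-10). Without WT control replicate 2, in which photosynthesis transcripts stood higher, the photosynthesis median was -1.10 (adjusted p = 1.22e-23).

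**Figure D4:**
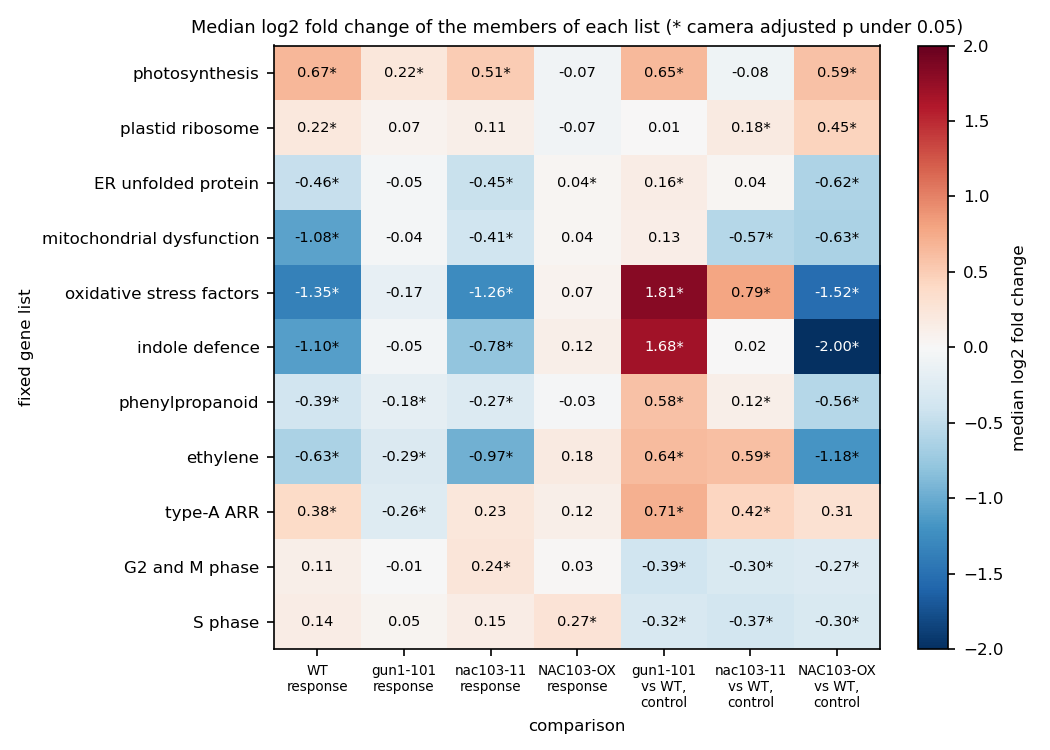
Median log2 fold change of the members of fixed gene lists (vertical axis) in the 4 responses to spectinomycin and the 3 genotype comparisons on control medium (horizontal axis), with a star where the camera adjusted p was under 0.05. The oxidative-stress transcription factor genes had medians of -1.35 in the WT response and 1.81 in gun1-101 against WT on control medium.

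On control medium, without the antibiotic, the indole defence gene CYP82C2 (AT4G31970) in gun1-101 was at 432 ± 5.63 against 6.08 ± 1.54 CPM (log2 fold change 6.13 ± 0.085, adjusted p = 3.38e-36), and CYP79B2 (AT4G39950), MYB51 and ERF6 were higher (log2 fold changes 2.91 ± 0.054, 2.02 ± 0.044 and 1.98 ± 0.051, highest adjusted p = 3.23e-31). CYP82C3 (AT4G31950) was at least 49.1-fold higher, against the floor of 3 counts over the WT group. Between gun1-101 and WT on control medium 7921 genes differed, 4826 higher and 3095 lower in gun1-101. Of 30 lists 13 were called, 9 up and 4 down, and 9 kept the call with an estimated correlation. Of the 50 nuclear photosynthesis genes measured, 41 were higher, 0 lower and 9 were not called (43 and 1 adjusted over the list alone). Their median was 0.65 (adjusted p = 3.45e-10, and adjusted p = 0.279 with an estimated correlation). Among the 7 oxidative-stress transcription factor genes measured, 7 were higher, 0 lower and 0 were not called (7 and 0 adjusted over the list alone). Their median was 1.81 (adjusted p = 2.02e-09). Of the 8 indole defence genes measured, 7 were higher, 1 lower and 0 were not called (7 and 1 adjusted over the list alone). Their median was 1.68 (adjusted p = 2.80e-07). Without WT control replicate 2, in which photosynthesis transcripts stood higher, the photosynthesis median was 0.91 (adjusted p = 4.68e-21).

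In nac103-11 on control medium, the orphan gene QQS (AT3G30720) was at 64.3 ± 1.35 against 1.44 ± 0.282 CPM (log2 fold change 5.49 ± 0.11, adjusted p = 6.49e-35), NRT2.6 at 29.8 ± 0.520 against 0.711 ± 0.299 CPM (log2 fold change 5.42 ± 0.17, adjusted p = 2.50e-27) and NRT1.8 at 230.4 ± 0.958 against 10.6 ± 0.404 CPM (log2 fold change 4.44 ± 0.074, adjusted p = 1.24e-37). The retroelement SADHU3-2 (AT3G42658), OCT1 (AT1G73220) and the aliphatic glucosinolate gene CYP79F2 (AT1G16400) differed too (log2 fold changes -3.28 ± 0.32, -3.25 ± 0.32 and -2.73 ± 0.19, highest adjusted p = 2.17e-11), and the iron response genes bHLH38 (AT3G56970) and OPT3 (AT4G16370) were lower (log2 fold changes -2.39 ± 0.26 and -0.84 ± 0.054, highest adjusted p = 2.02e-10). Between nac103-11 and WT on control medium 8481 genes differed, 4541 higher and 3940 lower in nac103-11. Of 30 lists 11 were called, 5 up and 6 down, and 6 kept the call with an estimated correlation. Among the 7 oxidative-stress transcription factor genes measured, 6 were higher, 0 lower and 1 was not called (6 and 0 adjusted over the list alone). Their median was 0.79 (adjusted p = 4.02e-04). Of the 15 iron deficiency genes measured, 1 was higher, 8 lower and 6 were not called (1 and 8 adjusted over the list alone). Their median was -0.84 (adjusted p = 7.62e-04). Among the 5 ethylene genes measured, 5 were higher, 0 lower and 0 were not called (5 and 0 adjusted over the list alone). Their median was 0.59 (adjusted p = 0.00379). The photosynthesis list was not called (median -0.085, adjusted p = 0.818), but was higher without WT control replicate 2, in which these genes stood higher (median 0.32, adjusted p = 0.00369).

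NAC103-OX on control medium had low levels of the genes that fell on spectinomycin in WT: PER4 was at 1.91 ± 0.400 against 285 ± 30.6 CPM (log2 fold change -7.22 ± 0.10, adjusted p = 5.15e-36) and NIA1 at 0.388 ± 0.198 against 61.6 ± 11.1 CPM (log2 fold change -7.29 ± 0.23, adjusted p = 4.78e-18), and F6'H1 (AT3G13610), MYB51, ERF6 and BIP2 were lower (log2 fold changes -6.42 ± 0.066, -2.64 ± 0.051, -3.11 ± 0.071 and -1.34 ± 0.048, highest adjusted p = 2.66e-26). EMB1030 (AT5G22800) was at 109 ± 1.75 against 8.57 ± 0.944 CPM (log2 fold change 3.67 ± 0.079, adjusted p = 1.82e-34), ACC2 (AT1G36180), a plastid acetyl-CoA carboxylase, at 88.6 ± 5.09 against 7.38 ± 0.186 CPM (log2 fold change 3.58 ± 0.083, adjusted p = 2.44e-33), and RAB18 (AT5G66400) and LTI78 of the abscisic acid response were higher (log2 fold changes 2.82 ± 0.23 and 2.18 ± 0.067, highest adjusted p = 4.65e-14). Between NAC103-OX and WT on control medium 8870 genes differed, 4453 higher and 4417 lower in NAC103-OX (4244 and 4600 with RLE size factors, 3830 and 4192 with DESeq2). Of the 892 genes that fell at least 2-fold in WT on spectinomycin, 852 were lower (median -1.80, or -1.77 with genes at 0 counts set to their bound), and of the 208 that rose, 155 were higher (median 1.12). Where every genotype was simulated at the WT means, so that only the WT control libraries were shared, such sets had medians of -0.016 to -0.0017 and 0.070 to 0.15 here, with at most 1 gene called. Across genes, which are not independent replicates, the correlation of the WT response with NAC103-OX against WT on control medium was 0.852, against 0.509 simulated for the shared WT control libraries alone, and the covariance was 0.399 against 0.0143. With no shared library, the WT response correlated at 0.792 with NAC103-OX against nac103-11 and at 0.801 with NAC103-OX against gun1-101 on control medium. Of 30 lists 15 were called, 6 up and 9 down, and 9 kept the call with an estimated correlation. Of the 32 ER unfolded-protein genes measured, 3 were higher, 24 lower and 5 were not called (3 and 25 adjusted over the list alone). Their median was -0.62 (adjusted p = 1.24e-10). Among the 32 nuclear genes of plastid ribosomal proteins measured, 30 were higher, 0 lower and 2 were not called (32 and 0 adjusted over the list alone). Their median was 0.45 (adjusted p = 1.24e-10). Of the 50 nuclear photosynthesis genes measured, 33 were higher, 2 lower and 15 were not called (35 and 2 adjusted over the list alone). Their median was 0.59 (adjusted p = 2.75e-08, and adjusted p = 0.273 with an estimated correlation). Without WT control replicate 2, in which photosynthesis transcripts stood higher, the photosynthesis median was 0.83 (adjusted p = 2.62e-17).

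**Figure D5:**
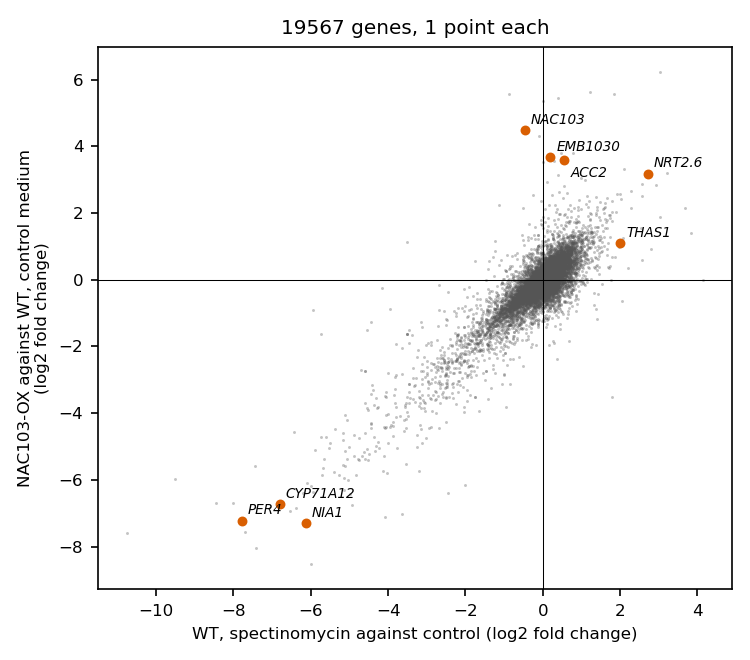
Log2 fold change of NAC103-OX against WT on control medium (vertical axis) by the WT response to spectinomycin (horizontal axis), with 1 point per gene and named genes labelled. The correlation across genes was 0.852.

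With gun1-101 and WT both on spectinomycin, PER4 in gun1-101 stood at 939.6 ± 51.1 against 1.27 ± 0.406 CPM (log2 fold change 9.50 ± 0.10, adjusted p = 4.45e-40) and CYP71A12 at 1935 ± 27.7 against 4.95 ± 0.0751 CPM (log2 fold change 8.61 ± 0.075, adjusted p = 4.84e-49), and ERF6, MYB51, PAL1 and ACS6 were higher (log2 fold changes 4.77 ± 0.065, 4.00 ± 0.050, 2.76 ± 0.047 and 4.50 ± 0.067, highest adjusted p = 8.78e-39). GLP6 (AT5G39100) was at least 61.0-fold higher, against the floor of 3 counts over the WT group. Between gun1-101 and WT on spectinomycin 11152 genes differed, 5413 higher and 5739 lower in gun1-101. The larger side turned with the setting, with numbers of 5819 and 5115 with RLE size factors, 5523 and 4525 with DESeq2 and 5834 and 5430 with only the groups of the contrast. Of the 892 genes that fell at least 2-fold in WT, 856 were higher in gun1-101 (median 2.68, or 2.67 with genes at 0 counts set to their bound). Of 30 lists 10 were called, 7 up and 3 down, and 7 kept the call with an estimated correlation. Among the 7 oxidative-stress transcription factor genes measured, 7 were higher, 0 lower and 0 were not called (7 and 0 adjusted over the list alone). Their median was 3.31 (adjusted p = 7.20e-09). Of the 32 ER unfolded-protein genes measured, 26 were higher, 1 lower and 5 were not called (27 and 1 adjusted over the list alone). Their median was 0.48 (adjusted p = 5.91e-08). Among the 17 mitochondrial dysfunction genes measured, 13 were higher, 0 lower and 4 were not called (13 and 0 adjusted over the list alone). Their median was 1.00 (adjusted p = 6.09e-07).

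In nac103-11 on spectinomycin PER4 was at 103 ± 3.54 against 1.27 ± 0.406 CPM (log2 fold change 6.31 ± 0.11, adjusted p = 2.95e-32), CYP71A12 at 138 ± 5.50 against 4.95 ± 0.0751 CPM (log2 fold change 4.80 ± 0.075, adjusted p = 3.88e-39) and QQS at 62.5 ± 3.15 against 1.46 ± 0.0792 CPM (log2 fold change 5.41 ± 0.11, adjusted p = 1.55e-35). GLP6 was at least 33.0-fold higher, against the floor of 3 counts over the WT group. Between nac103-11 and WT on spectinomycin 5211 genes differed, 3030 higher and 2181 lower in nac103-11, so that 58.1% were higher, against 68.2% of 4569 genes with DESeq2. Of the 892 genes that fell at least 2-fold in WT, 708 were higher in nac103-11 (median 0.99, or 0.99 with genes at 0 counts set to their bound). Of 30 lists 8 were called, 5 up and 3 down, and 4 kept the call with an estimated correlation. Of the 7 oxidative-stress transcription factor genes measured, 6 were higher, 0 lower and 1 was not called (6 and 0 adjusted over the list alone). Their median was 1.33 (adjusted p = 5.97e-11). Among the 12 phenylpropanoid genes measured, 10 were higher, 0 lower and 2 were not called (10 and 0 adjusted over the list alone). Their median was 0.30 (adjusted p = 1.44e-06). Of the 8 indole defence genes measured, 7 were higher, 1 lower and 0 were not called (7 and 1 adjusted over the list alone). Their median was 0.77 (adjusted p = 1.56e-05).

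In NAC103-OX on spectinomycin, EMB1030 was at 136 ± 5.38 against 9.79 ± 1.51 CPM (log2 fold change 3.79 ± 0.075, adjusted p = 1.93e-34), ACC2 at 104 ± 5.24 against 10.8 ± 1.08 CPM (log2 fold change 3.26 ± 0.076, adjusted p = 5.44e-32) and SRO3 (AT1G70440) at 11.2 ± 1.37 against 1.02 ± 0.0517 CPM (log2 fold change 3.44 ± 0.18, adjusted p = 2.21e-19). The glucosinolate genes BCAT4 (AT3G19710), CYP83A1 (AT4G13770) and CYP79B3 (AT2G22330) and CYP79B2 and the sulfate transporter gene SULTR3;5 (AT5G19600) differed from WT (log2 fold changes -1.79 ± 0.23, -1.70 ± 0.28, -1.01 ± 0.051, -0.86 ± 0.060 and -2.08 ± 0.26, highest adjusted p = 1.91e-05), and so did LTI78, RAB18 and BIP2 (log2 fold changes 0.89 ± 0.060, 1.75 ± 0.22 and -0.32 ± 0.048, highest adjusted p = 2.63e-06). Between NAC103-OX and WT on spectinomycin 3282 genes differed, 1654 higher and 1628 lower in NAC103-OX (1571 and 1583 without the filter). Of 30 lists 11 were called, 4 up and 7 down, and 6 kept the call with an estimated correlation. Among the 8 indole defence genes measured, 0 were higher, 6 lower and 2 were not called (0 and 6 adjusted over the list alone). Their median was -0.55 (adjusted p = 1.39e-08). Of the 26 G2 and M phase genes measured, 0 were higher, 9 lower and 17 were not called (0 and 15 adjusted over the list alone). Their median was -0.30 (adjusted p = 1.18e-05). Among the 32 ER unfolded-protein genes measured, 0 were higher, 14 lower and 18 were not called (0 and 17 adjusted over the list alone). Their median was -0.16 (adjusted p = 1.53e-05).

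The series asked how GUN1 and NAC103 relate, so the effects of gun1-101 and nac103-11 were set side by side. On spectinomycin PER4, CYP71A12, CYP81F2, ERF6 and F6'H1 (AT3G13610) were higher than in WT in both mutants, with log2 fold changes in gun1-101 and nac103-11 of 9.50 ± 0.10 and 6.31 ± 0.11 for PER4, 4.77 ± 0.065 and 1.91 ± 0.072 for ERF6 and 5.56 ± 0.058 and 3.14 ± 0.056 for F6'H1. On spectinomycin 2395 genes were higher and 1595 lower in both mutants, where independent lists would share 838 and 639.7, and 126 and 159 went opposite ways. The correlation of the 2 differences from WT was 0.797 across genes, which are not independent replicates, against 0.483 simulated for shared WT libraries alone, and the covariance was 0.396 against 0.0135. For the responses minus the WT response, the correlation was 0.580 against 0.481 simulated and the covariance 0.169 against 0.0281, with 647 genes higher and 461 lower in both, where independent lists would share 166 and 118, and 46 and 107 opposite. On control medium it was 0.624 against 0.467. Part of each excess may come from the shared WT libraries, since 3 libraries cannot be split into sets of at least 2 for each mutant.

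Responses that share no library were compared as well. The WT response correlated across genes at 0.730, 0.243 and 0.106 with those of nac103-11, gun1-101 and NAC103-OX. The gun1-101 and nac103-11 responses correlated at 0.332. NAC103-OX differences from WT on spectinomycin correlated at 0.0814 and 0.0994 with those of gun1-101 and nac103-11. Shared WT libraries alone gave 0.488 and 0.491 in simulation. The covariances were 0.0279 and 0.0174, against 0.0137 and 0.0130 simulated. NAC103-OX shared 809 higher and 805 lower genes with gun1-101, where independent lists would share 458 and 477, and 608 and 484 with nac103-11, where they would share 256 and 181. Opposite ways went 429 genes higher in gun1-101 and 294 lower (450.4 and 485 if independent), and 318 higher in nac103-11 and 138 lower (252 and 184). NAC103-OX responses minus WT correlated at 0.846 and 0.523 with those of gun1-101 and nac103-11 (0.492 and 0.491 simulated). Its differences on control medium gave -0.301 and -0.128 (0.480 and 0.495 simulated). Here too, shared WT libraries may add to an excess. Responses minus WT all subtract the WT response, which was not simulated, so their excess cannot show likeness. Intervals and floors given with counts cover counting error only.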

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

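The tests of patterns A, B and C were chosen after the results were seen, and the exchanges of libraries were chosen before the data were examined, as were the contrasts, lists and settings of the report. The results here are those whose response to spectinomycin differed between a genotype and WT by the test of the difference of responses. In gun1-101 this held for 4801 genes. By log2 difference the response was higher in PER4 (7.49), NIA1 (6.82), CYP71A12 (6.71), CYP81F2 (6.25), GSTU12 (5.63) and CYP71A13 (5.47), and lower in NRT2.6 (-6.50), RBCS1B (-4.33), RBCS3B (-2.99), PUP19 (-2.59) and LHCB2.2 (-2.29). Without WT control replicate 2 the values of RBCS3B and LHCB2.2 were -3.84 and -3.68. With few counts in a group, CYP71A18 (adjusted p = 1.24e-22), GLP6 (adjusted p = 4.44e-06), RBCS2B (adjusted p = 6.04e-05), SPL13A (adjusted p = 0.0437) and RLP31 (adjusted p = 0.0439) are given without a size, and SPL13A and RLP31 were not called when any 1 of several libraries was left out. The lists that responded higher were mitochondrial dysfunction genes (adjusted p = 1.49e-11), oxidative-stress transcription factor genes (adjusted p = 1.49e-11), ER unfolded-protein genes (adjusted p = 2.59e-09), indole defence genes (adjusted p = 4.56e-06), phenylpropanoid genes (adjusted p = 0.00289) and iron deficiency genes (adjusted p = 0.0487, adjusted p = 0.205 with an estimated correlation, up to 0.0996 with 1 library left out). Those that responded lower were nuclear photosynthesis genes (adjusted p = 2.28e-08, adjusted p = 0.353 with an estimated correlation), type-A response regulator genes (adjusted p = 4.07e-06) and nuclear genes of plastid ribosomal proteins (adjusted p = 0.00344, adjusted p = 0.205 with an estimated correlation).

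In nac103-11 the response differed from that of WT in 2300 genes. It was higher in PER4 (5.47), CYP71A12 (4.66), CYP81F2 (4.23), GSTU12 (3.87), NAC042 (3.41) and PXMT1 (3.39), and lower in NRT2.6 (-6.03), NRT1.8 (-3.97), NRT2:1 (-3.65), UMAMIT14 (-3.30), PIRL8 (-2.54), HA4 (-1.70), STP14 (-1.68) and MYB102 (-1.58). NRT2:1 was not called without WT spectinomycin replicate 1 (adjusted p = 0.177) nor PIRL8 without WT spectinomycin replicate 2 (adjusted p = 0.0809), and their values were -4.53 without nac103-11 spectinomycin replicate 3 and -3.17 without WT control replicate 1. With few counts in a group, GLP6 (adjusted p = 2.11e-07) and CYP71A18 (adjusted p = 3.55e-13) are given without a size. The lists that responded higher were mitochondrial dysfunction genes (adjusted p = 8.62e-07, adjusted p = 0.0546 with an estimated correlation), indole defence genes (adjusted p = 8.62e-07), oxidative-stress transcription factor genes (adjusted p = 1.09e-06), iron deficiency genes (adjusted p = 1.12e-04), phenylpropanoid genes (adjusted p = 0.0157, adjusted p = 0.101 with an estimated correlation) and fatty acid synthesis genes (adjusted p = 0.0177, adjusted p = 0.273 with an estimated correlation, up to 0.0788 with 1 library left out). Those that responded lower were nuclear genes of plastid ribosomal proteins (adjusted p = 0.0105, adjusted p = 0.313 with an estimated correlation), type-A response regulator genes (adjusted p = 0.0157, adjusted p = 0.0607 with an estimated correlation) and tetrapyrrole synthesis genes (adjusted p = 0.0270, adjusted p = 0.404 with an estimated correlation, up to 0.173 with 1 library left out).

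In NAC103-OX the response differed from that of WT in 6176 genes. It was higher in NIA1 (6.81) and PER4 (6.18), and lower in NRT2.6 (-4.02), RBCS1B (-2.53), BGLU7 (-2.36), UGT72B3 (-2.15) and CSLB04 (-2.09). RBCS1B was not called without NAC103-OX control replicate 2 (adjusted p = 0.0912). With few counts in a group, CCR4 (adjusted p = 6.22e-05), BGLU27 (adjusted p = 1.25e-05) and ABO3 (adjusted p = 1.40e-05) are given without a size, and CCR4 was not called without NAC103-OX spectinomycin replicate 2 (adjusted p = 0.0869). The lists that responded higher were oxidative-stress transcription factor genes (adjusted p = 5.94e-10), ER unfolded-protein genes (adjusted p = 8.67e-10), mitochondrial dysfunction genes (adjusted p = 1.49e-09), indole defence genes (adjusted p = 1.44e-04), phenylpropanoid genes (adjusted p = 0.00178), ethylene genes (adjusted p = 0.00407) and auxin genes (adjusted p = 0.0118). Those that responded lower were nuclear photosynthesis genes (adjusted p = 7.08e-12, adjusted p = 0.248 with an estimated correlation), nuclear genes of plastid ribosomal proteins (adjusted p = 1.06e-05), abscisic acid genes (adjusted p = 0.00553), tetrapyrrole synthesis genes (adjusted p = 0.0230, adjusted p = 0.426 with an estimated correlation, up to 0.0577 with 1 library left out) and type-A response regulator genes (adjusted p = 0.0488, adjusted p = 0.103 with an estimated correlation, up to 0.0796 with 1 library left out).

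Pattern A is the fall of defence and stress lists on spectinomycin in WT and far less in gun1-101. Spectinomycin clearing microbes from the medium cannot be told apart from an effect of GUN1. The median of the 64 members in gun1-101, -0.050 against -0.69 in WT, is the pattern itself. Plates or libraries handled group by group cannot be told apart from it either, since 0 of 8 batch tags held libraries of more than 1 group. A need for GUN1 in the fall of these genes remains a candidate explanation.

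Pattern B is that NAC103-OX on control medium lay close to WT on spectinomycin. Shared WT control libraries as its whole cause are excluded, since NAC103-OX minus nac103-11 on control medium, with no library shared, had a covariance of 0.481 and a correlation of 0.792 with the WT response. If NAC103-OX control plants had been kept on spectinomycin, the 1004 genes that fell in the other 3 genotypes would not fall in NAC103-OX. Their median there was -0.050, with 81 lower and 34 higher, against -0.74 for NAC103-OX minus WT on control medium. The 241 genes that rose in those genotypes had medians of -0.019 and 0.54. A response already at its end point through more NAC103 would give the same values, so these explanations cannot be told apart.

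Pattern C is that photosynthesis transcripts stood higher in WT on spectinomycin, and in WT control replicate 2 among the controls. In WT on spectinomycin, where RBCS1A gained 40.4 CPM, 6 other leaf transcripts gained a median of 1.85% of that and at most 169%, for CAB1, added after its values were seen, while CA1 gained -0.615% (without WT control replicate 2, 64.2 CPM, and 1.33, 153 and -0.240%). In WT control replicate 2, where RBCS1A gained 71.4 CPM, they gained a median of 0.532% and at most 125%, again for CAB1, and CA1 0.397%. Shoot tissue would bring all abundant leaf transcripts. All 6 gained unequally in replicate 2, and all but CA1 on spectinomycin. Reads of LHCB1.1 and LHCB1.2 may count to their close copy CAB1. Shoot tissue and a rise in the root cannot be told apart in either. At the preset correlation, a single library deciding the WT rise is excluded, since the list kept its call in all 6 fits without 1 WT library, with a highest adjusted p = 4.47e-11; with an estimated correlation it had no call (adjusted p = 0.219), and no biological explanation was tested.

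The libraries of each comparison were also exchanged between its groups, with each comparison fitted alone. For the 10 comparisons of 2 groups there are only 10 splits, too few to exclude chance. The real split called 6155, 2944, 9153 and 1298 genes in the responses of WT, gun1-101, nac103-11 and NAC103-OX, 6614, 7113 and 7267 in gun1-101, nac103-11 and NAC103-OX against WT on control medium and 11264, 5259 and 3609 on spectinomycin. In each, 1 of 10 splits, the real one, called as many, and the highest other called 0. For the NAC103-OX response minus that of WT, the real split called 5466 genes and the highest other of 100 called 4874. So 1 of 100 was as large. For gun1-101 it called 4212 and the highest other 6381, and for nac103-11 1836 and 3693, with 5 of 100 as large in each. Splits that call so many genes point to structure. Those for gun1-101 (6381, 6290, 5866 and 6029) exchanged 2 libraries on control medium and 0 on spectinomycin. Those for nac103-11 (3231, 3303, 3693 and 3108) exchanged 3 and 1. They put differences between genotypes into the contrast, as exchanges for NAC103-OX do, so counts over 100 splits cannot test chance.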

How the results depend on the processing

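The settings were chosen before the data were examined, except those for lists with RLE size factors, nuclear genes only and a left-out replicate, and the latter for the shared effects, chosen after seeing the data. Counts of changed genes kept within 1.5 times the main count in all 13 comparisons with DESeq2, RLE size factors, no filter, nuclear genes only, only the groups of the contrast and the replicate block. With DESeq2, 6941 genes changed in the WT response, 2885 up and 4056 down, and 4569 differed between nac103-11 and WT on spectinomycin. With the replicate number as a block (replicate block), 7985, 2226, 8814 and 1024 genes changed in the responses of WT, gun1-101, nac103-11 and NAC103-OX, 4869, 2347 and 6240 in the last 3 minus WT, 7937, 8505 and 8933 against WT on control medium and 11173, 5268 and 3313 on spectinomycin. The share of called genes that were higher crossed 50% in 4 comparisons. Over all settings and left-out replicates it ran from 44.4 to 50.5% in the nac103-11 response, from 47.7 to 50.2% in NAC103-OX on control medium, from 46.7 to 55.0% in gun1-101 on spectinomycin and from 49.8 to 56.4% in NAC103-OX on spectinomycin. It moved without crossing from 41.6 to 49.7%, 24.6 to 38.5% and 35.6 to 46.3% in the responses of WT, gun1-101 and NAC103-OX, from 53.7 to 64.5%, 51.8 to 63.1% and 50.8 to 57.9% in those of gun1-101, nac103-11 and NAC103-OX minus WT, from 53.5 to 64.2% and 50.6 to 56.4% in gun1-101 and nac103-11 on control medium and from 56.5 to 68.2% in nac103-11 on spectinomycin. Libraries with the same number showed no pairing, since the correlations of their residuals over 84 pairs ran from -0.0744 to 0.0771, and 9 of 24 libraries had their best match under their own number. Leaving out 1 replicate gave 6889 to 8155 genes for WT, 1589 to 1699 for gun1-101, 7720 to 8151 for nac103-11 and 483 to 711 for NAC103-OX, which was 990 with all libraries. For NAC103-OX, 5 of 6 such fits gave less than the main count divided by 1.5, which fewer samples would do, and the cause was not tested further. It gave 4198 to 5439, 1916 to 3284 and 5529 to 6772 for the responses minus WT, 6889 to 8147, 7427 to 8619 and 7924 to 8950 on control medium and 10141 to 10438, 4258 to 4548 and 2399 to 2850 on spectinomycin.

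The correlation of gun1-101 with nac103-11 on spectinomycin was 0.797, 0.843 over genes with a mean above 10 CPM and 0.780 to 0.796 with 1 replicate left out, and that of the responses minus WT was 0.580, 0.711 and 0.553 to 0.618. The cause was not tested. Of 131 called lists, 75 kept their call and 56 lost it with an estimated correlation, 2 lost it with RLE size factors, 1 with nuclear genes only, 3 with fry and 1 with the replicate block, the iron deficiency genes in the gun1-101 response minus WT (adjusted p = 0.0510). The iron deficiency genes in nac103-11 against WT on spectinomycin turned direction with fry (adjusted p = 0.109), which asks another question than camera, and the cause was not tested. With 1 replicate left out, 37 of 966 fits lost a list's call. Of the calls of named genes, 56 were lost with DESeq2, 20 with RLE size factors, 21 without the filter, 14 with nuclear genes only, 42 with only the groups of the contrast, 3 with the replicate block and 566 over the fits with 1 replicate left out, and no named gene turned direction. The CPM of GUN1 and NAC103 with raw library sizes moved by more than 1 SD in 10 of 16 group means. A pseudocount for FPKM or TPM did not apply. Few counts limit the results for NAC103 in nac103-11 and for the organelle genes in these poly(A) libraries. With 3 libraries per group, small differences of responses are limited as well.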

Other observations

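The tests of gene families and the comparison of the media were chosen after the main results were seen. Families were formed from symbols, 123 with at least 10 measured members, and tested with camera as the lists were. Only families whose members are all of 1 kind are given. In WT, among 55 WRKY transcription factor genes, 5 rose and 33 fell (adjusted p = 1.34e-07) and among 20 CPK calcium-dependent kinase genes, 1 rose and 12 fell (adjusted p = 2.84e-04). In gun1-101, among the same WRKY genes 1 rose and 16 fell (adjusted p = 0.00114, adjusted p = 0.115 with an estimated correlation), and among the CPK genes 0 rose and 3 fell (adjusted p = 0.627). Of the 4 WRKY genes with the smallest p in WT, log2 fold changes were -2.84 ± 0.10 in WT and -0.062 ± 0.062 in gun1-101 (adjusted p of the difference 6.54e-23) for WRKY53 and -1.37 ± 0.051 in WT and -0.35 ± 0.047 in gun1-101 (adjusted p of the difference 4.15e-16) for WRKY29, and WRKY31 and WRKY33 lay between these in gun1-101 (-0.17 and -0.19). In the gun1-101 response minus WT, among 55 WRKY genes, 27 responded higher and 4 lower (adjusted p = 2.07e-05).

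Some genes differed from WT by about the same amount on either medium, with log2 fold changes of at least 1.5 on each that lay within 0.6 of each other and a mean of at least 2 CPM. These were 109 genes in gun1-101, 104 of them higher, 38 in nac103-11, 34 higher, and 10 in NAC103-OX, 8 higher. In gun1-101 they held PP2-B14 (5.31 and 5.25), DIN11 (3.67 and 3.21) and HEI10 (-2.73 and -2.94), with the values on control medium and on spectinomycin. In nac103-11 they held QQS (5.49 and 5.41), SADHU3-2 (-3.28 and -3.74) and SEN1 (2.02 and 2.38), and in NAC103-OX EMB1030 (3.67 and 3.79), ACC2 (3.58 and 3.26) and XTH17 (1.57 and 1.96).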
